A study of Sus scrofa with 30 samples.

How the data were processed

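Native chromatin immunoprecipitation with sequencing from very few cells (ULI-NChIP-seq) measured trimethylation of histone H3 at lysine 4 (H3K4me3) and at lysine 27 (H3K27me3) in pig oocytes and in embryos made by fertilisation in vitro. The 30 libraries fell into 15 groups of 2. H3K4me3 was profiled at 8 stages, which were germinal vesicle (GV) oocyte, metaphase II (MII) oocyte, 1-cell, 2-cell, 4-cell, 8-cell, morula and blastocyst. It was also profiled in 4-cell embryos whose zygotes had received small interfering RNA against the H3K4 demethylases KDM5B and KDM5C (siKDM5BC). H3K27me3 was profiled at 6 stages, which were MII oocyte, 2-cell, 4-cell, 8-cell, morula and blastocyst. No library with a control siRNA was labelled, so untreated 4-cell libraries served as the control. The labels do not say whether the replicates came from separate collections, so the p-values measure only the spread between these libraries.

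Each library had 1 list of broad peaks. The submitters' processing notes name Bowtie2 2.4.1, MACS2 and the pig genome build susScr11. The MACS2 version, the use of an input control, the calling threshold and the read filters were not given in the sources used here. The lowest −log10 q in a list ran from 1.01 (H3K27me3 blastocyst replicate 2) to 1.59 (H3K4me3 blastocyst replicate 2). Peaks were called per library, not on pooled reads. In the deposited lists, the signal column is a fold enrichment ratio over the caller's background, and the next 2 columns are the authors' −log10 p and −log10 q, with no further normalization. Peak positions are deposited as 0-based start and end in base pairs (bp). The lists hold no read totals, so library depth is not stated in them. The caller's background, in reads per position, was recovered instead from the pair of fold enrichment and −log10 p seen most often in each list, taking the fold as (reads + 1)/(background + 1) and p as a Poisson tail. The best solution missed the deposited −log10 p by 1.28e-05 at most, and no second solution came closer than 0.000384. The background was used as a guide to depth only.

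Peaks on chromosomes 1 to 18 and X were used, and peaks on Y and on unplaced sequences were left out except where stated. Gene positions came from the annotation of the same assembly, with 19484 protein-coding genes, of which 762 were on X. The annotation used here gave no strand, so both ends of each gene were treated alike where transcription start sites had been planned. A gene counted as marked when a peak met the 1 kb on either side of either end by at least 1 bp. A peak was broad from 5 kb, and covered length was distal when more than 5 kb from every coding gene end. A gene gained a mark between 2 groups when neither library of the first and both libraries of the second were marked, and lost it in the opposite case. Each count was set beside the same count for the 2 mixed splits of the same 4 libraries, each of which joins 1 library of either group. A mixed split calls a gene only where the replicates of both groups disagree on it. Its count is held down by the group whose replicates agree more or hold fewer marks. It therefore does not measure what missed marks or depth in 1 group alone would give. With 2 libraries per group no test per gene was run.

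Stage effects on covered length (log2), broad share and distal share were tested with permutation tests of the F statistic, one-sided in F, with 100000 random assignments of libraries to stages and seed 1. They formed 1 family of 4 tests with Benjamini-Hochberg (BH) adjustment. Contrasts of stage means used exact permutation tests, two-sided, over 70 splits of 4 stages against 4 (smallest p possible 0.0286) or 15 splits of 4 against 2 (smallest p possible 0.0667). The siKDM5BC libraries were compared with 4-cell libraries by an exact permutation test, two-sided, whose smallest p possible was 0.333, and by the pooled SD between replicates of the 9 H3K4me3 groups. Gene lists were tested with Fisher's exact test, two-sided, against all other genes able to gain or lose the mark, with BH adjustment over 170 tests. Odds ratios carry 95% intervals on the log scale. Genes are not independent replicates. Shares of genes in single libraries carry Wilson 95% binomial intervals where given, for counting error only. The Jaccard index is the shared covered length of 2 libraries over their joint covered length.

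The 18 gene lists, fixed before the data were examined along with the comparisons, tests and first set of alternatives, were: HOX cluster, other developmental transcription factors, pluripotency and inner cell mass, trophectoderm, hypoblast, oocyte and maternal-effect, genome activation, ribosomal proteins, proteasome, respiratory complex I, glycolysis, H3K4 methylation enzymes, Polycomb and H3K27 demethylases, DNA methylation, imprinted, olfactory receptors, cumulus and granulosa cells, and sperm. Of 404 symbols listed one by one, 376 were matched in the annotation, and the remaining lists were matched by symbol pattern. The olfactory receptor pattern matched no annotated coding gene, so that list was not analysed here. Named genes followed a rule fixed at the same time. From each list and contrast it took up to 4 members that gained and 4 that lost the mark, ordered by the change in mean peak-covered bp within 5 kb of an end. It also took the 10 genes with the largest change up and down in mean peak-covered bp within 50 kb of an end, at least 200 kb apart, where both libraries of one group lay above both of the other. KDM5B, KDM5C, POU5F1, SOX2, NANOG, CDX2, GATA3, GATA6, GDF9, BMP15 and ZP3 were always followed. Values within 5 kb are those of the end with more covered bp in that library, and values within 50 kb those of the end with the larger change. Genes without a symbol other than a locus number were passed over in the 50 kb part.

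Alternatives were a peak minimum of 3 on the −log10 q scale, a fold minimum of 3, all sequences, windows of 2.5 kb, 50% of a window covered, peaks under 3 kb apart joined, broad from 10 kb, distal beyond 2 kb, an equal number of strongest peaks (37481 per library), libraries as units, covered length in Mb without logs, a replicate block, and leaving out each library. Fold minimums of 3.5 and 4, the assignment of each gene to the end with H3K4me3 in more libraries, and leaving out the 1-cell or 8-cell stage were added after the data were seen. The calling of gains and losses was tested on simulated data with 200 planted changes in each direction and 10% of marks dropped per library. It recovered 83% of planted gains and 88% of planted losses, with 105 gains and 108 losses called among other genes. Each change was planted in both libraries, and marks of unchanged genes were dropped at random at 1 rate. Real replicates differed more, as in H3K27me3 morula libraries with 953 and 1170 marked genes, 539 in both. These rates therefore do not carry over to the data. Of 500 random lists, 1.4% had p under 0.05, as did 100% of 200 planted lists. The F test passed 0.05 in 3% of 200 simulations with no effect. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.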

Results

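ULI-NChIP-seq peak lists described H3K4me3, a mark of active and poised promoters, and H3K27me3, the repressive mark of Polycomb complexes, from the pig oocyte to the blastocyst. There were 16 H3K4me3 libraries over 8 stages, 12 H3K27me3 libraries over 6 stages and 2 H3K4me3 libraries of siKDM5BC 4-cell embryos, with 2 libraries in every group. Read totals are not in the lists. The background recovered from them, a guide to depth, ran from 0.957 reads per position (MII oocyte replicate 1) to 2.25 (1-cell replicate 1) for H3K4me3. For H3K27me3 it ran from 0.170 (morula replicate 1) to 1.11 (2-cell replicate 1). H3K4me3 lists held 37481 peaks (4-cell replicate 2) to 119878 peaks (2-cell replicate 1) on chromosomes 1 to 18 and X. H3K27me3 lists held 2358 peaks (2-cell replicate 2) to 80700 peaks (blastocyst replicate 2). All coordinates are those of the pig build susScr11, and values after ± are SDs of 2 libraries.

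The stage series addressed how the H3K4me3 landscape is reset between oocyte and blastocyst. In the peaks as called, H3K4me3 lay nearest to genes in 4-cell embryos, and among the 8 stages the largest share of it in wide domains was in morulae and blastocysts. Peaks more than 5 kb from a coding gene end made up 43.7% ± 5.21 (n = 2) of the covered length at the 4-cell stage, against 68.4% ± 0.477 in MII oocytes and 59.2% ± 0.0620 to 65.3% ± 1.85 at the 6 other stages. Domains of 5 kb or wider held 2.87% ± 1.56 of the covered length at the 4-cell stage, 3.89% ± 2.90 in MII oocytes, 19.5% ± 0.272 in morulae and 22.7% ± 1.27 in blastocysts. The distal share changed across stages by 24.8 percentage points (permutation test of F over 16 libraries, one-sided, p = 0.00155, BH 0.0062), and the broad share by 19.8 points (p = 0.00634, BH 0.00852). Covered length was 118 Mb ± 14.6 in 2-cell embryos, 44.0 Mb ± 17.5 in 4-cell embryos, 73.8 Mb ± 10.9 in 8-cell embryos and 134 Mb ± 10.9 in morulae. It did not pass its test across stages (1.66 log2 units between the extremes, permutation p = 0.0511, BH 0.0511). Without the 1-cell stage, whose libraries covered 68.9 and 142 Mb, the same range gave a permutation p of 0.0121, and with only peaks of −log10 q 3 or more the range was 7.49 log2 units. With that minimum the broad share no longer passed (permutation p = 0.178), and the stage with the highest mean was the MII oocyte (51.7% and 16.8%, over 0.234 and 1.00 Mb), above blastocysts (29.4% and 30.9%) and morulae (26.0% and 27.5%). Joining peaks under 3 kb apart put the broad share from the 4-cell stage on −15.8 points from that of earlier stages (exact permutation p = 0.0571). The ranking by wide domains therefore depended on how peaks were called. The lowest fold was 3.11 and 3.31 in the 4-cell lists, above every other H3K4me3 list except GV oocyte replicate 2. A part of that floor in the low distal share was not excluded. The distal share kept its test result in all 23 repeats.

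**Figure D1:**
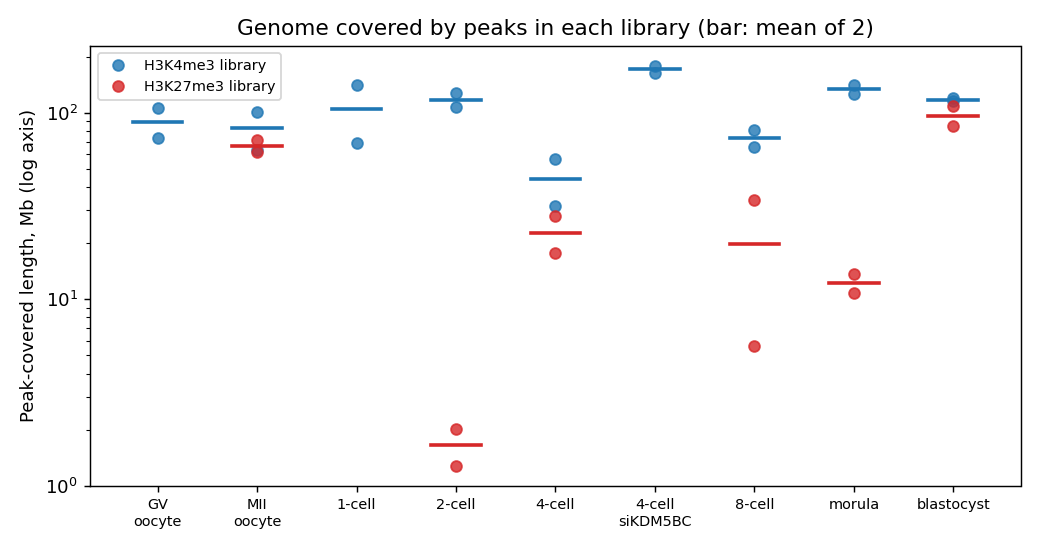
Length of the genome covered by peaks in each library (Mb, log axis) by stage; blue, H3K4me3; red, H3K27me3; each point is 1 library and each bar the mean of 2. H3K4me3 was lowest at the 4-cell stage (44.0 Mb) and H3K27me3 at the 2-cell stage (1.64 Mb).

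The split at the 4-cell stage, when the major wave of pig genome activation takes place, did not separate the H3K4me3 stages. From the 4-cell stage on, mean log2 covered length differed from that of earlier stages by −0.19 (exact permutation test, 4 stage means against 4, two-sided, p = 0.714) and mean broad share by 5.59 points (exact p = 0.4). Peaks with −log10 q of 3 or more covered 0.617 Mb ± 0.541 in MII oocytes, 0.889 Mb ± 0.742 in 1-cell and 0.992 Mb ± 0.326 in 2-cell embryos (n = 2 each). They covered 18.1 Mb ± 13.5 in GV oocytes, 20.8 Mb ± 12.2 in 4-cell embryos and 86.1 Mb ± 4.13 in blastocysts. With this minimum, the stages from the 4-cell stage on lay above the earlier ones by 4.86 log2 units (exact permutation p = 0.0286, the smallest possible), while their broad share differed by −3.69 points. Joining peaks under 3 kb apart also turned the broad-share difference, to −15.8 points (exact p = 0.0571).

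**Figure D2:**
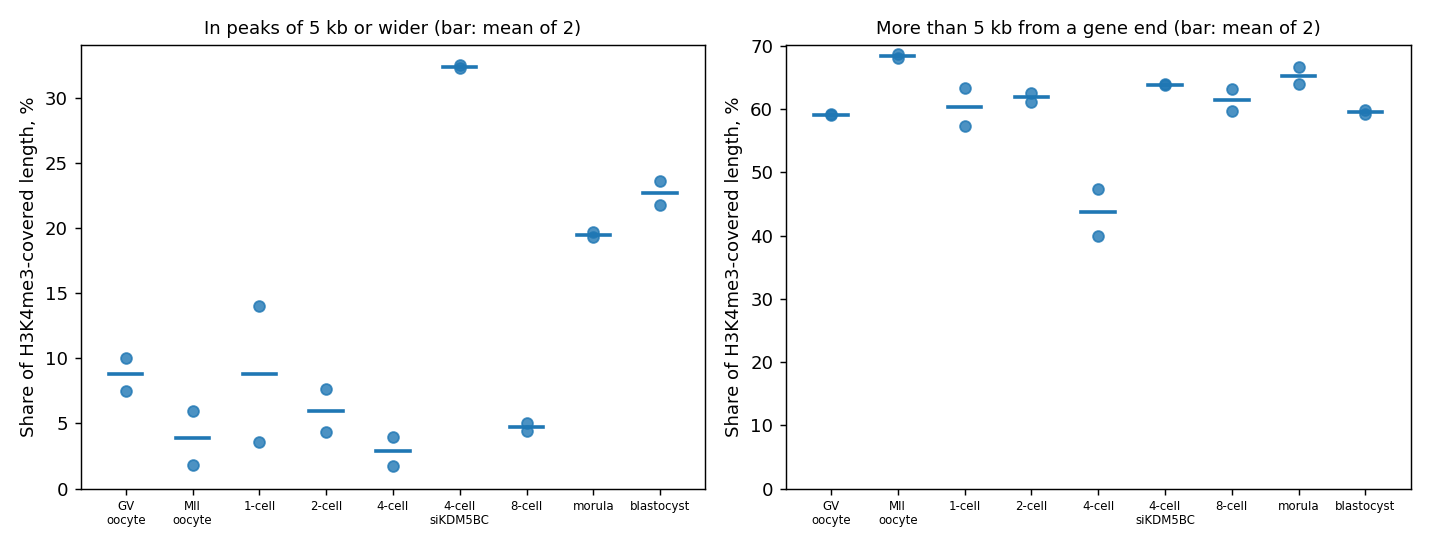
Share of H3K4me3-covered length (%) in peaks of 5 kb or wider (left) and more than 5 kb from a coding gene end (right), by stage, with 1 point per library and a bar at the mean of 2. siKDM5BC embryos had the largest share in peaks of 5 kb or wider (32.4%), and untreated 4-cell embryos the smallest distal share (43.7%).

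From the 2-cell to the 4-cell stage, 652 coding genes lost H3K4me3 at their ends and 157 gained it, while peaks as a whole covered 2.68 times as much in 2-cell as in 4-cell embryos. With a fold minimum of 3.5 no such drop remained (27.2 and 38.5 Mb in 2-cell, 39.6 and 25.9 Mb in 4-cell libraries). Among the largest decreases, the stretch within 50 kb of an end of the amino acid transporter gene SLC6A17 (gene 100156430, chromosome 4, 109919153 to 109974235) had 54671 and 49637 bp of peaks in the 2-cell libraries against 8622 and 5524 bp in the 4-cell libraries. Around the splicing factor gene U2AF1 (chromosome 13, 206244772 to 206257697) it went from 61324 and 45382 bp to 15552 and 8708 bp, and around EDN2 (chromosome 6, 169751956 to 169758011) from 63437 and 42259 bp to 16538 and 8391 bp. The largest increase, around OSBPL8 (chromosome 5, 39568136 to 39744655), went from 7517 and 6638 bp to 23389 and 17831 bp. The lists' losses included the neural crest factor SOX10 and ZIC4, 2 of 35 marked HOX genes (HOXD10, HOXB3), the cofactor of de novo DNA methylation DNMT3L, the nuclear receptor gene NR5A2 and LEFTY2. SOX10 had 8134 and 5802 bp of peaks within 5 kb in the 2-cell libraries and 2856 and 1460 bp in the 4-cell libraries. DNMT3L had 5097 and 4821 bp, then 1553 and 1247 bp. The imprinted gene MAGEL2 went from no peak to 2933 and 732 bp.

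Mixed splits of the same 4 libraries gave up to 203 genes in 1 direction, fewer than the 652 losses and more than the 157 gains. No gene list passed in either direction. The counts turn with peak strength: with −log10 q of 3 or more 0 genes lost the mark and 6775 gained it, and the HOX (22 of 34, BH 0.0206) and developmental factor lists (62 of 108, BH 0.000325) passed. Only 15 genes were then marked in both 2-cell libraries, so these passes tell which genes the 4-cell lists marked and not what changed. With windows of 2.5 kb, 1 of the 13 list genes named as lost was still called, without 1 library the gains were 226 to 544 and the losses 794 to 1620, and with 50% of a window covered 375 and 1028.

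Between MII oocyte and blastocyst, 1198 genes gained H3K4me3 at an end and 805 lost it, against at most 51 in a mixed split. The mixed count was held down by the agreement of the blastocyst libraries, which marked 14644 and 14614 genes, 14339 of them in both. Oocyte genes (4 of 13 lost, 2 of 9 gained) and imprinted genes (2 of 15 lost, 4 of 6 gained) changed in both directions, and of the pluripotency genes 2 of 5 gained the mark and 0 of 19 lost it. ZP3, which encodes a zona pellucida glycoprotein (gene 396927, chromosome 3, 9934760 to 9944924), had 1829 and 2810 bp of peaks within 5 kb in MII libraries and none in blastocyst libraries. NLRP9, NLRP5 and WEE2 were the other 3 of 13 marked oocyte and maternal-effect genes that lost the mark. DNMT1, the maintenance DNA methyltransferase, went from 1798 and 2705 bp to 0, and the growth factor gene IGF2 from 4073 and 5498 bp to 986 and 954 bp. Among gains, the NODAL co-receptor gene TDGF1 (chromosome 13, 29537874 to 29544686) went from 210 and 0 bp to 6549 and 6069 bp, KLF17 from 288 and 1966 bp to 7098 and 7143 bp, and the trophectoderm list's TEAD3 from 304 and 2073 bp to 10001 and 9134 bp. The imprinted genes NNAT, PEG3, NAP1L5 and NDN gained the mark, as did RBBP5, a subunit of H3K4 methyltransferases, and EED, a subunit of Polycomb repressive complex 2.

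Of the genes taken for the largest change in either direction over the same interval within 50 kb of an end, ACTN1 (chromosome 7, 92550132 to 92644842), which encodes an actin cross-linker, had 1552 and 3443 bp in MII libraries and 69721 and 64203 bp in blastocyst libraries. The membrane-cytoskeleton linker gene EZR went from 1008 and 1189 bp to 52002 and 54735 bp, and JARID2, a Polycomb cofactor gene, from 4193 and 16051 bp to 60313 and 62151 bp. In the other direction, the peroxidasin gene PXDN (chromosome 3, 132306288 to 132362853) went from 44286 and 67905 bp to 2404 and 2083 bp, and CROCC2 from 48284 and 78683 bp to 5160 and 4636 bp. No list passed BH in this contrast; the oocyte losses had a Fisher exact p of 0.0118 (BH 0.335) and the imprinted gains 0.047 (BH 0.711). With −log10 q of 3 or more, MII oocytes had 7 genes marked in both libraries, and the counts became 13276 gains and 0 losses. At that minimum, where a gain says only that the blastocyst lists marked the gene, gains of ribosomal protein (74 of 76), proteasome (43 of 45), complex I (37 of 37), glycolysis (19 of 19) and developmental factor genes (94 of 112) passed BH 0.05, and oocyte genes gained less often than others (13 of 31 against 69.6%, BH 0.0266). With 50% of a window covered there were 4930 gains and 372 losses. Gains came to 3801 without MII replicate 2, and losses to 1326 without MII replicate 1.

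Injection of siRNA against KDM5B and KDM5C addressed their part in H3K4me3 removal by the 4-cell stage. H3K4me3 peaks covered 172 Mb ± 10.2 in siKDM5BC 4-cell embryos against 44.0 Mb ± 17.5 in untreated ones (n = 2 each), 3.90 times as much. Domains of 5 kb or wider held 32.4% ± 0.204 of the covered length against 2.87% ± 1.56. They numbered 6526 and 5992 against 328 and 79, a ratio of means of 30.8 that was 19.1 without 4-cell replicate 2 and 79.2 without replicate 1. At gene ends, 833 genes gained H3K4me3 and 29 lost it. Gains included the oocyte genes ZP3 (no peak within 5 kb in untreated embryos, 2347 and 2833 bp in siKDM5BC), NLRP5 and WEE2, the developmental factors SOX10, ZIC4, SIX3, HOXB3 and HOXD10, and NR5A2, LEFTY2 and DNMT3L. DNMT3L (chromosome 13, 207119025 to 207141990) went from 1553 and 1247 bp to 8364 and 8622 bp.

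The largest increases within 50 kb filled nearly the whole window. The cation-chloride cotransporter gene SLC12A7 (chromosome 16, 79356868 to 79396652) had 29484 and 12184 bp in untreated libraries and 98738 and 97652 bp in siKDM5BC libraries. PXDN went from 30360 and 8542 bp to 95337 and 97695 bp, TSNARE1 from 17543 and 8106 bp to 89881 and 88462 bp, and the endoderm factor gene GATA5 from 20325 and 9091 bp to 91490 and 90517 bp. At POU5F1, marked at an end in both groups, peaks within 5 kb went from 1704 and 2311 bp to 6099 and 5900 bp, and at CDX2, a trophectoderm factor gene, from 5074 and 2549 bp to 10001 and 9299 bp. At KDM5B itself the lists held 4689 and 3121 bp against 4831 and 6905 bp, and at KDM5C 1215 and 1957 bp against 2676 and 1837 bp, and the transcripts were not measured in these libraries.

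The log2 difference in covered length, 2.02, was 5.21 times the pooled SD between replicates of the 9 H3K4me3 groups (0.39), and the difference in broad share, 29.5 points, was 10.2 times its own. With 2 libraries against 2 the exact permutation p was 0.333, the smallest possible. Mixed splits gave up to 117 genes in 1 direction, below the 833 gains and above the 29 losses. With windows of 2.5 kb, 6 of the 17 list genes named as gained were still called, without 1 library the gains were 1029 to 2158 and the losses 36 to 182, and with 50% of a window covered 2601 and 4. With −log10 q of 3 or more, gains of developmental factors (5 of 9, BH 0.0266) and losses of imprinted genes (3 of 9, BH 0.00803) passed. They did not in the main run (3 of 5, BH 0.711, and 0 of 17, BH 1) or with windows of 2.5 kb (no developmental factor able to gain, and 0 of 17).

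Genes that gained H3K4me3 in siKDM5BC embryos had more often been marked before the 4-cell stage than the other unmarked genes. Of the 652 genes that lost the mark between the 2-cell and 4-cell stages, 456 (69.9%) gained it in siKDM5BC, against 9.37% of the other genes unmarked in both 4-cell libraries. The same 2 untreated 4-cell libraries define the loss and the gain, so marks that their lists missed would count as lost and regained. Among the 4677 genes unmarked in both 4-cell libraries, the odds ratio of a gain was 22.5 (95% interval 18.5 to 27.4) for genes marked in 2-cell embryos, 17.7 for GV oocytes, 16.1 for MII oocytes and 15.9 for 1-cell embryos. It was 2.42 (1.85 to 3.16) for 8-cell embryos, 3.90 for morulae and 3.70 for blastocysts. Genes with H3K27me3 in MII oocytes also gained more often (6.54, interval 5.08 to 8.41), as did those with it in blastocysts (3.02, 2.39 to 3.81) and morulae (2.33, 1.27 to 4.27, BH 0.0155), relations examined after the data were seen. Those with it in 4-cell (0.656, 0.408 to 1.05) and 8-cell embryos (0.749, 0.336 to 1.67) did not, and none with it in both 2-cell libraries gained. Fisher exact p was 9.09e-10 or below for each of the 7 H3K4me3 stages, with a BH value of 1.31e-09 for the weakest over 13 groups. The early marks were weak, with 15 genes marked in both 2-cell libraries at −log10 q of 3 or more. The lowest −log10 q was 1.25 and 1.35 in the 2-cell lists, 1.49 and 1.51 in the 4-cell lists and 1.08 and 1.12 in the 8-cell lists. In the siKDM5BC lists it was 1.25 and 1.41, with a lowest fold of 2.70 and 2.86 against 3.11 and 3.31 in the 4-cell lists. A difference in calling threshold between lists was neither shown nor excluded.

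**Figure D3:**
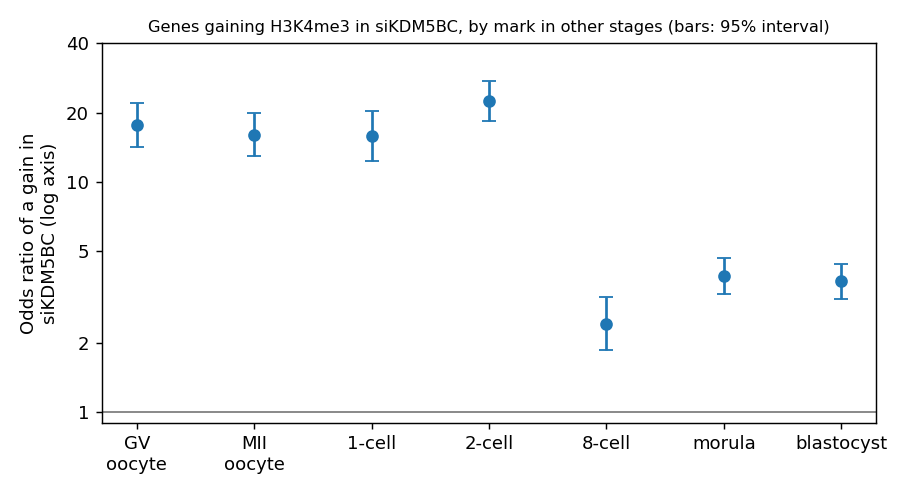
Odds ratio (log axis) that a gene unmarked in both 4-cell libraries gained H3K4me3 in siKDM5BC embryos, for genes marked in both libraries of each other stage against the rest; bars are 95% intervals over 4677 genes. The ratios were 15.9 to 22.5 for oocytes to 2-cell embryos and 2.42 to 3.90 for 8-cell embryos to blastocysts.

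In the peaks as called, H3K27me3 was nearly absent from 2-cell embryos and had its largest covered length in blastocysts. It covered 66.7 Mb ± 6.79 in MII oocytes, 1.64 Mb ± 0.516 in 2-cell embryos, 22.8 Mb ± 7.22 at the 4-cell, 19.9 Mb ± 20.2 at the 8-cell and 12.2 Mb ± 1.99 at the morula stage, and 96.8 Mb ± 17.1 in blastocysts (n = 2 each). From MII oocyte to 2-cell embryo 2160 genes lost the mark, 97.5% of the 2216 marked in both MII libraries, and 3 gained it. All 24 HOX genes and all 71 other developmental factor genes marked in both MII libraries lost it, as did the 12 trophectoderm, 9 hypoblast and 6 pluripotency genes so marked, and 9 of 10 imprinted genes. The T-cell and trophectoderm factor gene GATA3 (gene 733631, chromosome 10, 63367684 to 63397977) had 8631 and 9645 bp of H3K27me3 peaks within 5 kb in MII oocytes and none in 2-cell embryos. HOXA6, IRX4, CDX2 and GATA6 went likewise to 0, as did the imprinted genes ASCL2 (10001 and 10001 bp), GRB10, DLK1 and IGF2.

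Among the genes ranked by their decrease within 50 kb, PXDN had 97964 and 92895 bp in MII oocytes and 1483 and 574 bp in 2-cell embryos. THBS2 (chromosome 1, 854473 to 882467), which encodes a matrix glycoprotein, went from 93977 and 86759 bp to 0, and SLC12A7 from 90033 and 86790 bp to 457 and 0 bp. POU5F1, SOX2, GDF9, BMP15 and ZP3 had no H3K27me3 peak within 5 kb in either group. Covered length changed across the 6 stages by 5.90 log2 units (permutation test of F over 12 libraries, one-sided, p = 0.00639, BH 0.00852). The 4 stages between MII oocyte and blastocyst lay −3.18 log2 units from those 2 stages (exact permutation test on stage means, two-sided, p = 0.0667, the smallest possible). Mixed splits gave up to 13 genes, but each such call needed a mark in a 2-cell library, where only 125 and 89 genes had one. The background was 1.11 and 0.796 reads per position in the 2-cell libraries and 0.977 and 0.626 in the MII libraries. With −log10 q of 3 or more 310 genes lost the mark, with 50% of a window covered 968, and without 2-cell replicate 1 or 2 the gains were 37 and 64.

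From morula to blastocyst 2101 genes gained H3K27me3 and 7 lost it, and developmental regulators led the gains. Of 57 unmarked developmental factor genes 33 gained it, against 11.6% of other genes (Fisher exact p = 6.83e-17, BH 1.16e-14), as did 10 of 25 HOX genes (p = 0.000299, BH 0.0208) and 11 of 30 ribosomal protein genes (p = 0.000368, BH 0.0208). HOXC12 (gene 100518782, chromosome 5, 19167174 to 19169684) went from 0 bp to 8183 and 6793 bp within 5 kb, and TBX15 from 527 and 1063 bp to 6064 and 10001 bp. Among the 33 were HAND1 (0 bp to 3664 and 7339 bp) and EOMES, which the trophectoderm list also holds, SOX17 (773 and 781 bp to 5916 and 6508 bp) and GATA6, also on the hypoblast list, and OTX2, also on the pluripotency list. Those lists did not pass, with gains at 4 of 16 trophectoderm (BH 0.883), 7 of 16 hypoblast (BH 0.0564) and 1 of 24 pluripotency genes (BH 1), and neither did the imprinted genes (6 of 14, BH 0.115). Within 50 kb the largest gains lay at GMDS (chromosome 7, 849088 to 1285563; 16643 and 21825 bp to 79637 and 83335 bp) and THBS2, and at the X-linked genes ADGRG4 (1519 and 5125 bp to 50344 and 71109 bp), PRPS2, FAM58A and RTL5. POU5F1 and SOX2 had no H3K27me3 peak within 5 kb in either stage.

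Mixed splits gave up to 64 genes. The background was 0.170 and 0.182 reads per position in morula and 0.397 and 0.456 in blastocyst libraries, so depth differed with stage. With −log10 q of 3 or more the gains numbered 350, and the HOX (11.4% against 1.80% of other genes, BH 0.0508) and ribosomal (5.71% against 1.80%, BH 0.327) calls were lost, on 4 gains each, where the main counts were 10 of 25 and 11 of 30 against 11.7%. With windows of 2.5 kb the HOX call stayed (BH 8.06e-05) and the ribosomal one was lost (37.9% against 16.5%, BH 0.267). Without blastocyst replicate 1 the gains were 3859, without morula replicate 1 the losses were 107, and with 50% of a window covered there were 844 gains and 0 losses.

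Over the whole series, HOX genes carried H3K27me3 in 75.0% ± 3.93 of cases in MII oocytes, in none of either 2-cell or 4-cell library, in 20.8% ± 1.96 in morulae and in 68.1% ± 1.96 in blastocysts. The other developmental factors went from 68.1% ± 1.22 in MII oocytes to 0% in 2-cell embryos, 40.1% ± 4.27 in morulae and 82.3% ± 3.05 in blastocysts. Of the 2216 genes marked in both MII libraries, 1077 (48.6%) were marked in both blastocyst libraries, where 374 would be so by independence, and 885 of them were unmarked in all 2-cell, 4-cell and 8-cell libraries. In all, 3289 genes were marked in both blastocyst libraries, so most of these had not been marked in both MII libraries. The highest Jaccard index between an MII and a blastocyst library was 0.103. Of 170 list tests over the 5 contrasts, 3 passed BH 0.05, all among the H3K27me3 gains in the blastocyst, and 11 had an unadjusted Fisher exact p under 0.05. In that contrast the gains were 1 of 24 pluripotency, 4 of 16 trophectoderm, 6 of 28 oocyte, 3 of 16 genome activation, 3 of 41 proteasome, 1 of 34 complex I, 1 of 19 glycolysis, 1 of 17 H3K4 methylation, 5 of 24 Polycomb, 0 of 15 DNA methylation, 5 of 19 cumulus and granulosa and 2 of 20 sperm genes. None of these passed.

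**Figure D4:**
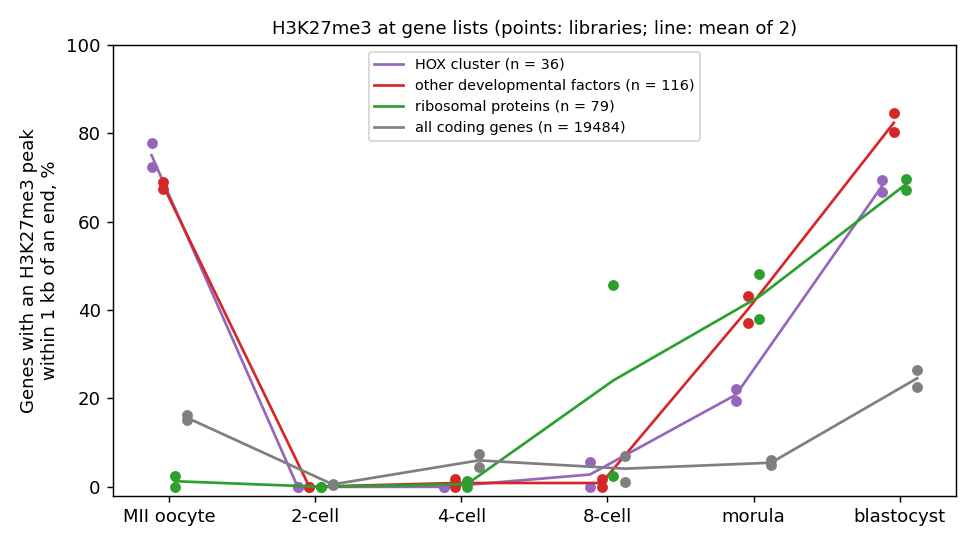
Share of genes (%) with an H3K27me3 peak within 1 kb of an end, by stage, for 3 gene lists and all coding genes; points are libraries and lines join the means of 2. HOX genes went from 75.0% in MII oocytes to 0% in 2-cell embryos and 68.1% in blastocysts.

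The 2 antibodies together addressed at which genes both marks had peaks, as at the poised promoters of developmental regulators. The marks came from separate libraries, so peaks of both at 1 gene end need not come from the same cells or alleles. Without strand, that end need not be the promoter. Both marks met at the same gene end in 1554 genes of MII oocytes, among them 81 of the 152 HOX and other developmental factor genes. In 2-cell, 4-cell and 8-cell embryos no gene of these 152 had both, because none had H3K27me3 in both libraries. Those counts therefore add nothing to the H3K27me3 series. In morulae 32 had both and in blastocysts 95. In all, 631 genes had both marks at the same end in MII oocytes and again in blastocysts, where independence gives 197 (odds ratio 5.97, 95% interval 5.33 to 6.68). Genes with H3K27me3 carried H3K4me3 more often than others in MII oocytes (odds ratio 3.34, interval 3.002 to 3.72), 8-cell embryos (2.14, 1.42 to 3.22), morulae (4.45, 3.25 to 6.09) and blastocysts (1.98, 1.80 to 2.19), and less often in 4-cell embryos (0.420, 0.350 to 0.504). In 2-cell embryos, with 20 H3K27me3-marked genes, the test did not pass (0.505, 0.209 to 1.22; Fisher exact p = 0.14), and it passed without H3K27me3 2-cell replicate 1 (0.351) or replicate 2 (0.491). The BH values over the 6 stages were 0.000152 or below for the other 5. With 50% of a window covered the blastocyst ratio was 0.978 (Fisher exact p = 0.726), the 4-cell ratio 0.511 (p = 0.123) and the 2-cell ratio 1.87. With −log10 q of 3 or more the 4-cell ratio was 1.13 and the 8-cell ratio 3.57 (Fisher exact p = 0.379). The 8-cell ratio was 1.17 without H3K27me3 8-cell replicate 1 and 5.90 without H3K4me3 replicate 1, and the MII ratio 5.59 without H3K4me3 MII replicate 1.

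H3K4me3 replicates resembled each other most in morulae and blastocysts. The Jaccard index of the 2 libraries was 0.631 for H3K4me3 in blastocysts, 0.605 in morulae and 0.545 in siKDM5BC embryos, and 0.208 in 1-cell embryos. For H3K27me3 it was 0.405 in MII oocytes, 0.387 in blastocysts and 0.0753 in 2-cell embryos. In 10 of 15 groups the replicates were closer to each other than to any library of another group with the same antibody. The exceptions were GV oocytes, MII oocytes, 1-cell and 2-cell embryos, each closest to a siKDM5BC library, and H3K27me3 in 8-cell embryos, closest to a 4-cell library. The siKDM5BC libraries shared more with 2-cell libraries (mean index 0.330) than the untreated 4-cell libraries did (0.183), and less with 8-cell libraries (0.149 against 0.242), although the index also depends on covered length, which was greatest in siKDM5BC.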

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

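The tests of unplaced sequences, of library batch, of the 2-cell pattern as the whole rise, of depth in 1-cell and 2-cell libraries and of ribosomal pseudogenes were chosen after the results were seen, and so was the rule that voided the 2 tests of X dose.

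H3K4me3 peaks covered 3.90 times as much of the genome in siKDM5BC 4-cell embryos as in untreated ones. The tables argue against library depth as the whole cause. The background was 1.22 and 1.10 reads per position in siKDM5BC and 1.25 and 1.12 in untreated 4-cell libraries, where depth as the cause had predicted a higher one in siKDM5BC. The log2 difference was still 1.69 (pooled SD 0.83) with a fold minimum of 3.5, above the lowest value of every list. Peaks on the unplaced sequences kept in the siKDM5BC lists are no part of the difference of 2.02 (pooled SD 0.39), which was measured without them. That value is the main result itself, so it does not test any other difference in processing. A library batch, or other mapping, filtering or calling of the siKDM5BC reads, cannot be told apart from the siRNA. Only 1 of the 2 groups had lists with unplaced sequences, and there was no control siRNA. Keeping the 2-cell pattern, after an siRNA whose knockdown was not measured, is a candidate biological explanation only of which genes gained the mark. The odds ratio of a gain was 22.5 for genes marked in 2-cell embryos against 2.42 for 8-cell embryos, in a test that either order was open to. The tables argue against it as the whole rise, by an amount that depended on the fold minimum. With all peaks, siKDM5BC libraries covered 179 and 164 Mb against 128 and 108 Mb in 2-cell libraries, with a broad share of 32.4% against 5.99%. At the fold minimum of 3.5 they lay above 2-cell libraries by 1.68 log2 units (pooled SD 0.83). That minimum cut the 2-cell lists to 27.2 and 38.5 Mb. The broad share was then 47.6% and 44.8% against 12.8% and 8.10%. The odds ratios for GV oocytes (17.7), MII oocytes (16.1) and 1-cell embryos (15.9) had intervals that overlapped the 2-cell one. The 2-cell pattern was therefore not singled out from earlier ones. The 2-cell marks were weak, guanine and cytosine content was not examined because no genome sequence was used here, and delayed development of injected embryos was not tested.

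X-linked gene ends carried H3K4me3 less often than autosomal ones in 1-cell embryos (13.6%, Wilson 95% interval 11.4 to 16.3, and 57.0%, 53.4 to 60.4, against 65.7% and 76.7%) and in 2-cell embryos (49.6%, 46.1 to 53.1, and 51.6%, 48.0 to 55.1, against 76.7% and 76.5%), a mean difference of −35.9 and −26.0 points, against −4.21 to −12.7 points in GV and MII oocytes, 8-cell embryos, morulae and blastocysts, −19.0 in untreated 4-cell embryos and −8.94 in siKDM5BC embryos of the same stage. The tables argue against lower depth: the lowest background of the 4 libraries was 1.32 reads per position, against 0.957 and 1.36 in MII oocytes, and of the 8 H3K4me3 libraries with a background below it 7 had a smaller X difference than each of the 4 (all 8: −7.32 to −21.4 points, the 4: −19.7 to −52.0). A smaller X dose, with embryos of both sexes in a sample, would also hold at later stages and in both 4-cell groups. Yet the mean difference was −12.7 points in 8-cell embryos, −4.21 in morulae and −7.26 in blastocysts. In GV and MII oocytes it was −7.24 and −6.26. The siKDM5BC and untreated 4-cell values differed too. These values argue against dose alone. A dose effect limited to weak peaks stays open, since peaks of −log10 q 3 or more covered 0.889 Mb in 1-cell embryos and 87.0 Mb in morulae. The X share lay above the autosomal share counted with a fold minimum raised by the dose, as had been predicted for such a dose, in all 4 libraries. That comparison was judged unable to decide only after its values were seen, because the raised minimum left at most 10.7% of autosomal genes marked for a dose of 0.75 and 0.0320% for a dose of 0.5, so that nearly any X share would have passed.

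Ribosomal protein genes carried H3K27me3 in 43.0% ± 7.16 of cases in morulae and 68.4% ± 1.79 in blastocysts (SD, n = 2), and in 2.53% and 45.6% in the 2 8-cell libraries, a split within a stage that leaves a technical cause open. Carry-over from the strongest H3K4me3 sites would mark the genes with the highest H3K4me3 fold most, yet outside the developmental lists 10.4% of the top 10% of genes and 25.2% of the lower 50% carried H3K27me3 in both blastocyst libraries, a ratio of 0.412. Only 2 ribosomal genes lay in that top 10%, both marked, and 43 of 76 outside it were marked. The lower 50% can also hold unlisted genes with H3K27me3 of their own, so the ratio does not decide the question for ribosomal genes. Reads shared with ribosomal pseudogenes had been taken to be present at every stage, yet in MII oocytes, of 51 H3K4me3-marked ribosomal genes 0 carried H3K27me3 in both libraries. Copies that carry the mark only at later stages would give the same result. No pseudogene was examined, so shared reads stay open. Very high transcription stays open, since 29.3% of 41 other very highly transcribed genes were marked against 16.7% of the rest (Fisher exact p = 0.0553). No biological explanation was tested, and at −log10 q of 3 or more the list's gains no longer passed (BH 0.327), with 4 of 70 genes (5.71%) against 1.80% of others, where the main shares were 36.7% and 11.7%.

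Peaks on unplaced sequences, used only in the repeats with all sequences, numbered 1212 and 1087 in the siKDM5BC libraries and 0 in the other 28 libraries. Genes on X carried H3K27me3 more often than autosomal genes in blastocysts (by 8.72 and 14.3 points) and less often in 4-cell embryos (by −3.95 and −2.62 points), and the difference between the stages was not tested. Chromosome Y, used only in the same repeats, held 46 and 53 H3K4me3 peaks in the blastocyst libraries against 4 to 16 in the 4 oocyte libraries. Other embryos lay between or near these, with 47 and 29 in morulae, 30 and 40 at the 8-cell stage, 31 and 15 in untreated 4-cell and 34 and 27 in siKDM5BC libraries. Higher counts than in oocytes were therefore not particular to blastocysts, and the source of the Y peaks was not examined.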

How the results depend on the processing

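The minimum fold enrichments of 3.5 and 4, the assignment of genes to the end with H3K4me3 in more libraries and the runs without the 1-cell or 8-cell stage were chosen after the data were seen. Of 296 repeats of the main results, 228 kept direction and side of the threshold (for counts, stayed within 1.5 times), 50 values moved, 9 passed and 3 no longer passed a threshold, and 6 reversed. Of 70 repeats for named genes, 47 kept their calls. The lists hold no read totals, so what depth limits was not measured beyond the recovered background.

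With −log10 q of 3 or more, H3K4me3 covered length varied across stages by 7.49 log2 units (permutation p = 0.00069) and broad share by 29.3 points (p = 0.178). The stages from the 4-cell stage on differed from earlier ones by 4.86 log2 units and −3.69 points of broad share, and siKDM5BC from 4-cell embryos by 42.3 points. From 2-cell to 4-cell 6775 genes gained and 0 lost H3K4me3, from MII to blastocyst 13276 and 0, and 112 lost it in siKDM5BC. H3K27me3 was gained by 0 and lost by 310 genes from MII to 2-cell, and gained by 350 and lost by 1 from morula to blastocyst. List tests past BH 0.05 numbered 11, and odds ratios of both marks were 1.13 (4-cell) and 3.57 (8-cell). The 2-cell odds ratio could not be computed, with 0 genes marked by H3K27me3 alone. The near-empty early lists at this minimum show why the early counts moved.

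With 50% of a window covered, gains and losses were 375 and 1028 (2-cell to 4-cell), 4930 and 372 (MII to blastocyst), 2601 and 4 (siKDM5BC), 0 and 968 (H3K27me3, MII to 2-cell), and 844 and 0 (morula to blastocyst). Odds ratios of both marks were 1.87 (2-cell), 0.511 (4-cell) and 0.978 (blastocyst). With windows of 2.5 kb 7 genes gained H3K27me3 in 2-cell embryos. With 1 assigned end, 14 genes lost H3K4me3 in siKDM5BC, 1 gained H3K27me3 in 2-cell embryos and 4 lost it in blastocysts. The siKDM5BC difference in broad share was 33.7 points with a fold minimum of 3, 45.2 with peaks joined, 13.2 with broad from 10 kb and 41.3 with equal numbers of strongest peaks. Joining peaks turned the broad-share difference from the 4-cell stage on to −15.8 points. Libraries as units gave −3.18 log2 units for H3K27me3 with a permutation p of 0.00808, by the larger number of units. Without the 1-cell stage the H3K4me3 range stayed 1.66 with a permutation p of 0.0121, as its widely spread pair left the error. Except where a reason is given, the cause was not tested.

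Leaving out 1 library gave 1.24 to 2.08 log2 units for H3K4me3 across stages, passing 0.05 without MII replicate 2 (permutation p = 0.0496), 1-cell replicate 1 (0.0172), 1-cell replicate 2 (0.0197) or 4-cell replicate 1 (0.0439). The siKDM5BC log2 difference was 2.44 without 4-cell replicate 1 and 1.60 without replicate 2. A lone library meets the calling rule more easily, so counts rose by construction and no named list gene was lost. From 2-cell to 4-cell, gains were 226 to 544, with 456 and 544 without 2-cell replicates 1 and 2 and 448 without 4-cell replicate 2, and losses 794 to 1620, with 1052 without 2-cell replicate 2 and 1620 without 4-cell replicate 1. From MII to blastocyst, gains were 1315 to 3801, the highest without MII replicate 2, and losses 906 to 1326, the highest without MII replicate 1. For siKDM5BC, gains were 1029 to 2158, the highest without 4-cell replicate 1, and losses 36 to 182, with 83 and 182 without 4-cell replicates 1 and 2 and 74 without siKDM5BC replicate 1. H3K27me3 gains in 2-cell embryos were 4 to 64, with 5 without MII replicate 2 and 37 and 64 without 2-cell replicates 1 and 2. H3K27me3 gains in blastocysts were 2356 to 3859, the highest without blastocyst replicate 1, and losses 107 and 79 without morula replicates 1 and 2 and 16 and 14 without blastocyst replicates 1 and 2. The 2-cell odds ratio was 0.351 to 0.599, passing without either H3K27me3 2-cell library. The MII ratio was 5.59 without H3K4me3 MII replicate 1, and the 8-cell ratio 5.90 without H3K4me3 replicate 1 and 1.17 without H3K27me3 replicate 1.

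With a replicate block, the permutation p was 0.0797 for H3K4me3 covered length across stages, 0.00989 for H3K27me3, 0.0164 for broad share and 0.00363 for distal share. Replicate numbers were not shown to pair libraries (r = 0.0449 between the replicate differences of 4-cell and siKDM5BC embryos, across 23925 bins that are not independent).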

Other observations

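The Fisher tests of gene lists in this part were planned. The comparison by H3K27me3 in MII oocytes and blastocysts was chosen, and the regions were set side by side, after their values were seen.

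PXDN and CROCC2 were among the 10 genes with the largest decrease within 50 kb after the MII stage for both marks. Around the peroxidasin gene PXDN, MII libraries had 44286 and 67905 bp of H3K4me3 and 97964 and 92895 bp of H3K27me3 peaks within 50 kb. CROCC2 had 48284 and 78683 bp of H3K4me3 and 87532 and 78558 bp of H3K27me3. In siKDM5BC embryos PXDN had 95337 and 97695 bp of H3K4me3. Genes with H3K27me3 in MII oocytes made up 17.8% of the genes that gained H3K4me3 in siKDM5BC embryos and 3.20% of the other genes unmarked in 4-cell embryos, and genes with H3K27me3 in blastocysts 15.5% and 5.72%.

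Imprinted genes carried H3K27me3 in 45.5% ± 0 of cases in MII oocytes, 2.27% ± 3.21 in 2-cell embryos and 68.2% ± 6.43 in blastocysts (SD, n = 2), against 15.7%, 0.549% and 24.6% of all coding genes. Oocyte and maternal-effect genes had it in 1.61% ± 2.28 of cases in MII oocytes and 33.9% ± 6.84 in blastocysts, where LHX8, ZP4, ZAR1 and BTG4 were among the 6 of 28 that gained it (BH 0.965). Genes of cumulus and granulosa cells, which surround oocytes in the follicle, carried H3K27me3 in 23.7% ± 3.72 of cases in MII oocytes, against the same 15.7% of all coding genes. Sperm genes gained H3K4me3 in 3 of 6 and lost it in 3 of 9 cases between MII oocyte and blastocyst, against 26.6% and 7.28% of other genes, and the losses had a Fisher exact p of 0.0233 (BH 0.496). HOX genes carried H3K4me3 in 88.9% to 100% of cases on average in each of the 9 H3K4me3 groups, and all coding genes in 66.8% to 79.8%.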
